A study of Mus musculus with 6 samples.

How the data were processed

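The series holds 6 polyA RNA libraries of mouse liver, 3 labelled DKO (mTR and Wrn deleted) and 3 labelled p21TKO (mTR, Wrn and p21 deleted), all of generation 3. Per the labels' protocols, RNA was isolated with TRIzol and libraries were made with a NEBNext Ultra kit. Strandedness is not given in the sources used here. The table deposited by the authors gives 1 FPKM value per gene and library. Per the submitters' processing notes, CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 were used. The same notes name the human builds GRCh38 and hg38, while the gene identifiers are mouse, so the build behind the values is not settled. Coordinates are those of GENCODE M21 (GRCm38), matched by gene identifier for 55480 of 55573 genes, and 93 were not matched.

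FPKM are not counts, so no count model was the main test. Multiplying FPKM by the union exon length of GENCODE M21 gave values that were whole multiples of a constant per library, within 0.02 reads, for 99.3% of values in each library and for 99.5% of genes. This gave whole reads and the FPKM denominators, between 19363285 and 27061291 reads, which are not in every library the sum over the listed genes. A gene at 0 was given the FPKM that 3 reads would have made as its limit, which covers counting error only.

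Values were used as deposited, with no further scaling. Genes with a mean FPKM of at least 1 were tested on log2(FPKM + 1) with limma 3.58.1 (trend, two-sided, R 4.3.3) and Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was called. Of 45 gene lists fixed before the data were examined, 39 had at least 5 tested members and were tested with camera at a preset correlation of 0.01. They were also tested with an estimated correlation, with fry, and as ssGSEA scores (weight 0.25) by an exact permutation test and limma. On simulated values for these libraries, with 50 genes changed per size among 9352 genes in the fit, the gene test recovered 28% of genes changed by 1, 74% by 2, 90% by 3 and 94% by 5 on the log2 scale, and called 7 of 9110 unchanged genes. The changed genes were drawn only from those with a mean log2(FPKM + 1) above 2. Each gene was simulated independently, without the variation that genes of the real libraries share. These rates therefore do not cover lower genes or shared variation.

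The genes named in the text follow a rule fixed before the data were examined. It takes the 3 targeted genes, the 10 largest changes in each direction among named, non-pseudogene genes past the threshold with separated groups (if fewer than 5 pass in both directions together, the 5 with the smallest p in each direction), up to 4 members per list with the smallest p, and 5 sex-linked genes. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as such or belong to a test of positions. Alternatives fixed beforehand were the pseudocount, the filter, scaling between libraries, the variance model, a replicate block, limma voom on recovered reads, an added size threshold, other list tests and leaving out each library. Alternatives added after the values were seen were a sex term from Y-linked transcripts, its combination with voom, leaving out pseudogenes, and leaving mitochondrially encoded genes out of the FPKM total. The tests of positions and of pseudogene parents (BLAST 2.17.0, best protein-coding transcript, e-value under 1e-20), run in Python 3.11.15 with scipy 1.17.1, were also chosen after the values were seen. Figures were drawn with matplotlib 3.10.9.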

Results

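Liver RNA of generation 3 mice of 2 genotypes was profiled by polyA RNA sequencing. The control mice, named DKO, were described as lacking mTR, the gene for the RNA template of telomerase (Terc), and Wrn, a RecQ helicase gene. The p21TKO mice were described as lacking p21 (Cdkn1a), a cyclin-dependent kinase inhibitor, in addition. Each genotype had 3 libraries, and the stated question was which pathways differ after loss of p21. Values were deposited as FPKM for 55573 genes. The FPKM denominators corresponded to 24027504, 21516838 and 22223530 reads in DKO replicates 1 to 3 and 19363285, 22954755 and 27061291 reads in p21TKO replicates 1 to 3, and between 18271 and 19535 genes were above 0 per library. The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries. With 3 libraries against 3, no exact permutation test can give a two-sided p under 0.1.

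Cdkn1a transcripts were present in every library and were not lower in the libraries labelled p21TKO. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727, GRCm38) stood at 0.76, 1.79 and 0.41 FPKM (65, 137 and 32 reads) in DKO replicates 1 to 3. The libraries labelled p21TKO held 1.41, 11.05 and 6.5 FPKM (97, 901 and 625 reads). The group means were 0.986 ± 0.72 FPKM (SD, n = 3) and 6.32 ± 4.82 FPKM (SD, n = 3). The log2 difference of 1.66 (SE 0.59) did not pass the test (limma adjusted p = 0.523), and it did pass without p21TKO replicate 1 (2.32, limma adjusted p = 0.0224). That replicate was the only p21TKO library with Y-linked transcripts, so leaving it out sets the groups further apart by sex. The Cdkn1a difference was 2.43 within libraries without Y-linked transcripts and 0.28 within those with them. With a sex term it was 1.36 and did not pass (limma adjusted p = 0.6461). The deleted part of the gene is not given in the sources used here and the values cover all exons, so they cannot check the deletion. The groups are therefore named by their labels throughout, and every direction given for p21TKO rests on those labels. Wrn (ENSMUSG00000031583, chromosome 8, 33234384 to 33385527) stood at 0.256 ± 0.052 FPKM (SD, n = 3) in DKO and 0.239 ± 0.035 FPKM (SD, n = 3) in p21TKO, with 36 to 48 reads in each library, so Wrn transcripts were present and its deletion is unchecked too. Terc (ENSMUSG00000064796, chromosome 3, 96414437 to 96414859) was at 0 in all 6 libraries, where 3 reads would have given 0.262 to 0.366 FPKM. Terc RNA carries no polyA tail, so a polyA library says little about it.

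**Figure D1:**
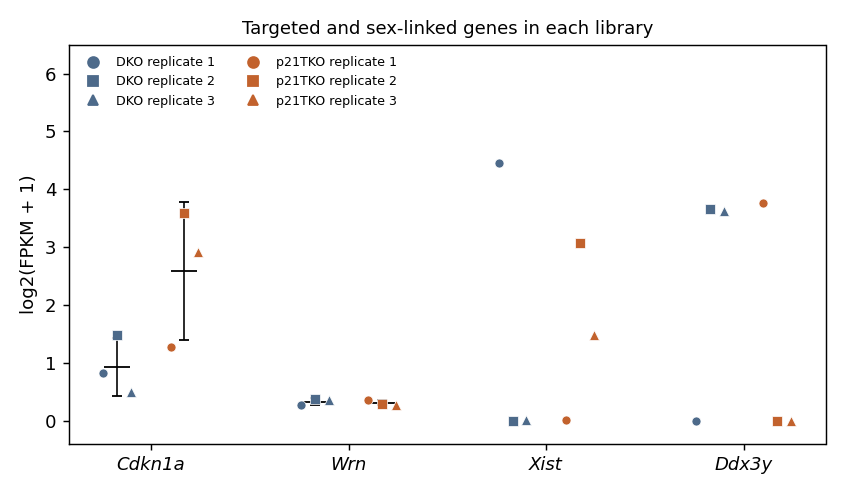
Expression of Cdkn1a, Wrn, Xist and Ddx3y in each of the 6 libraries as log2(FPKM + 1), with points for libraries and, for Cdkn1a and Wrn, bars for the mean and SD of 3 libraries. Cdkn1a was highest in p21TKO replicates 2 and 3 (11.05 and 6.5 FPKM), and Xist and Ddx3y divided the libraries across both groups.

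The labels give no sex, and the sex-linked genes showed that each group held both sexes in different proportions. Ddx3y, a Y-linked RNA helicase gene, stood at 11.64, 11.36 and 12.56 FPKM in DKO replicates 2 and 3 and p21TKO replicate 1 and had no reads in the other libraries. Eif2s3y, Kdm5d and Uty divided the libraries in the same way. Xist, the transcript of the inactive X chromosome, stood at 20.85 FPKM in DKO replicate 1 and at 7.35 and 1.79 FPKM in p21TKO replicates 2 and 3. The first principal component held 57.2% of the variance and set p21TKO replicates 2 and 3 (44.4 and 56.6) apart from the other 4 libraries (-34.6 to -7.7). p21TKO replicate 1 was closest to DKO replicate 2 (Pearson r = 0.978 across genes, which are not independent replicates).

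Of 9538 genes tested, 3 were higher and 4 lower in the libraries labelled p21TKO (limma, Benjamini-Hochberg adjusted p under 0.05). The named genes that fell were Ctse, Ren1 and A2ml1. Ctse, which encodes the aspartic protease cathepsin E (ENSMUSG00000004552, chromosome 1, 131638306 to 131675505), went from 10.3 ± 1.76 FPKM (SD, n = 3) in DKO to 0.043 ± 0.021 FPKM (SD, n = 3), a log2 difference of -3.42 (SE 0.16, limma adjusted p = 0.0017). Ren1, the renin gene (ENSMUSG00000070645, chromosome 1, 133350510 to 133360325), went from 6.96 ± 2.80 to 0.049 ± 0.043 FPKM (SD, n = 3 each), with a log2 difference of -2.87 (SE 0.25, limma adjusted p = 0.0167). A2ml1, an alpha-2-macroglobulin-like gene (ENSMUSG00000047228, chromosome 6, 128539821 to 128581608), went from 3.57 ± 0.814 to 0.117 ± 0.073 FPKM, with a log2 difference of -2.02 (SE 0.18, limma adjusted p = 0.0167). These differences are on the log2(FPKM + 1) scale, which understates changes of low genes.

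The other 4 called genes were processed pseudogenes, outside the rule for named genes and named here after their values were seen. Atp6v0c-ps2 stood at 1.81 ± 0.192 FPKM in DKO and 101 ± 41.6 FPKM in p21TKO (log2 difference 5.09, SE 0.33, limma adjusted p = 0.0084). Gm9825 (3.10, limma adjusted p = 0.0167) and Rps2-ps6 (2.45, limma adjusted p = 0.0167) were also higher, and Gm6969 was lower, at 76.5 ± 28.4 against 1.94 ± 1.03 FPKM (-4.72, limma adjusted p = 0.0167). Each is 96.5% to 99.8% identical to a protein-coding transcript, so reads could be divided between the copies and these values are uncertain. Of all 7 calls, only that of Ctse was also made by limma voom on recovered reads (adjusted p = 0.0403) and passed whichever library was left out. Without DKO replicates 1, 2 or 3 the calls kept were 2, 5 and 1 of the 7, and without p21TKO replicates 1, 2 or 3 they were 7, 2 and 2, with the total without p21TKO replicate 1 at 225 genes higher and 270 lower.

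**Figure D2:**
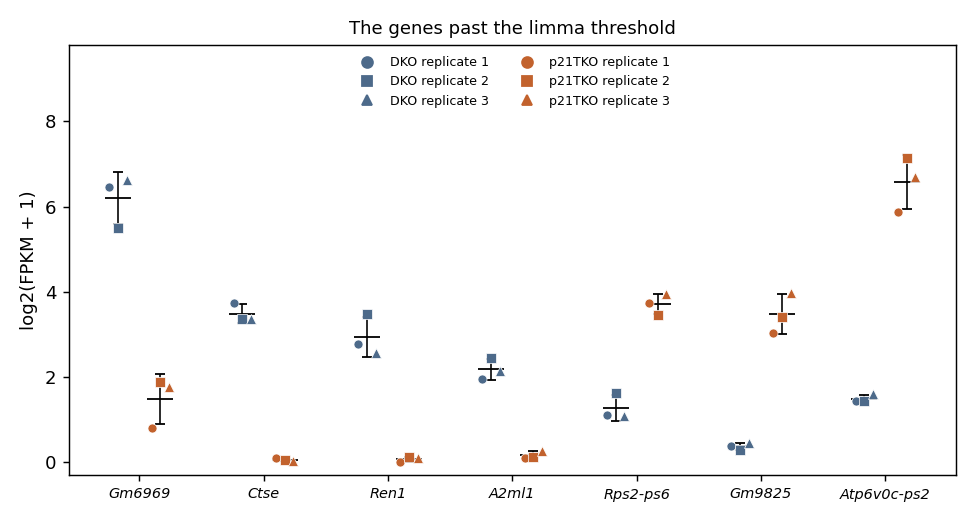
Expression of the 7 genes past the limma threshold in each library as log2(FPKM + 1), with bars for the mean and SD of 3 libraries per group. Ctse lay at 9.22 FPKM or above in the DKO libraries and at 0.065 FPKM or below in the libraries labelled p21TKO.

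The next genes by p, 5 in each direction including those above, did not pass. Pttg1, the securin gene, stood at 10.8 ± 2.06 FPKM in DKO and 0.91 ± 0.866 FPKM in p21TKO (-2.70, limma adjusted p = 0.0715). Hmga1, a chromatin-binding gene, was at 9.04 ± 1.61 and 2.87 ± 0.12 FPKM (-1.36, limma adjusted p = 0.0727), while its near-identical copy Hmga1b was at 0.99 ± 0.073 and 4.41 ± 0.961 FPKM (1.43, limma adjusted p = 0.0715). Nudt18 (1.30), Sertad3 (1.04), Slpi (1.99) and Nxt1 (0.84) had limma adjusted p from 0.103 to 0.3395. At an unadjusted p under 0.05 there were 895 genes (390 higher and 505 lower), where 477 are expected by chance. The 3 values of one group lay wholly above or below those of the other for 1471 genes, 15.4% of those tested, against 10% by chance.

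Genes that separated the groups were unusually frequent around Cdkn1a itself, a region examined after the values were seen. Of 179 genes with separated groups and an unadjusted limma p under 0.01, 14 (7.82%) started within 15 Mb of Cdkn1a on chromosome 17, against 246 of the other 9358 tested genes (2.63%; odds ratio 3.14, Fisher's exact test, two-sided p = 0.000377). They included Decr2, a peroxisomal dienoyl-CoA reductase gene, at 99.2 ± 1.61 FPKM in DKO and 22.8 ± 17.5 FPKM in p21TKO, and Tmem8, at 6.65 ± 0.067 and 3.15 ± 0.215 FPKM. Atp6v0c stood at 16.6 ± 2.15 and 7.61 ± 1.16 FPKM and Rnps1 at 4.29 ± 0.566 and 1.14 ± 0.574 FPKM. None of the 14 passed on its own (limma adjusted p from 0.0727 to 0.5154).

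**Figure D3:**
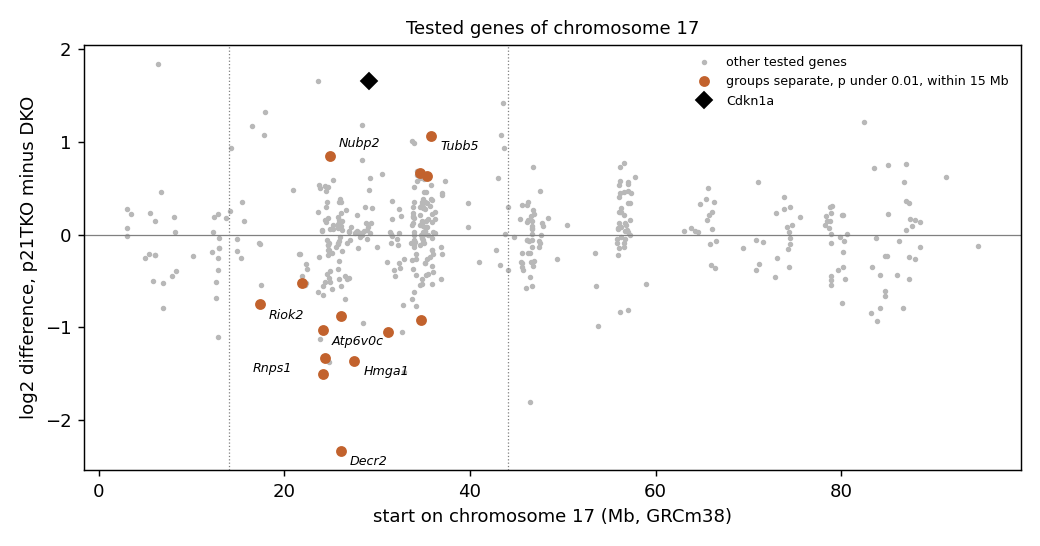
The log2 difference (p21TKO minus DKO) of each tested gene of chromosome 17 against its start in Mb (GRCm38), with Cdkn1a as a diamond and dotted lines 15 Mb to each side of it. The 14 coloured genes had separated groups and an unadjusted p under 0.01, and Decr2 had the lowest difference among them (-2.34).

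Gene lists fixed before the data were examined were compared next, to ask which pathways differed. Of 39 lists with at least 5 tested members, 9 were higher and 10 lower by camera with a preset inter-gene correlation of 0.01. With an estimated correlation 0 lists were called (smallest adjusted p = 0.594, 0 at an unadjusted p under 0.05). fry, which tests whether the genes of a list move on balance one way, called 0 (smallest adjusted p = 0.29, 5 at an unadjusted p under 0.05), and limma on the ssGSEA scores called 0 (smallest adjusted p = 0.215, 4 at an unadjusted p under 0.05). No member of any list passed the gene test over all genes. Adjusted over the list alone, Rhbg passed among the pericentral genes and mt-Nd4l among the mitochondrially encoded genes. All examples from the lists below that lack a test of their own did not pass (limma), and their values are given as levels.

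**Figure D4:**
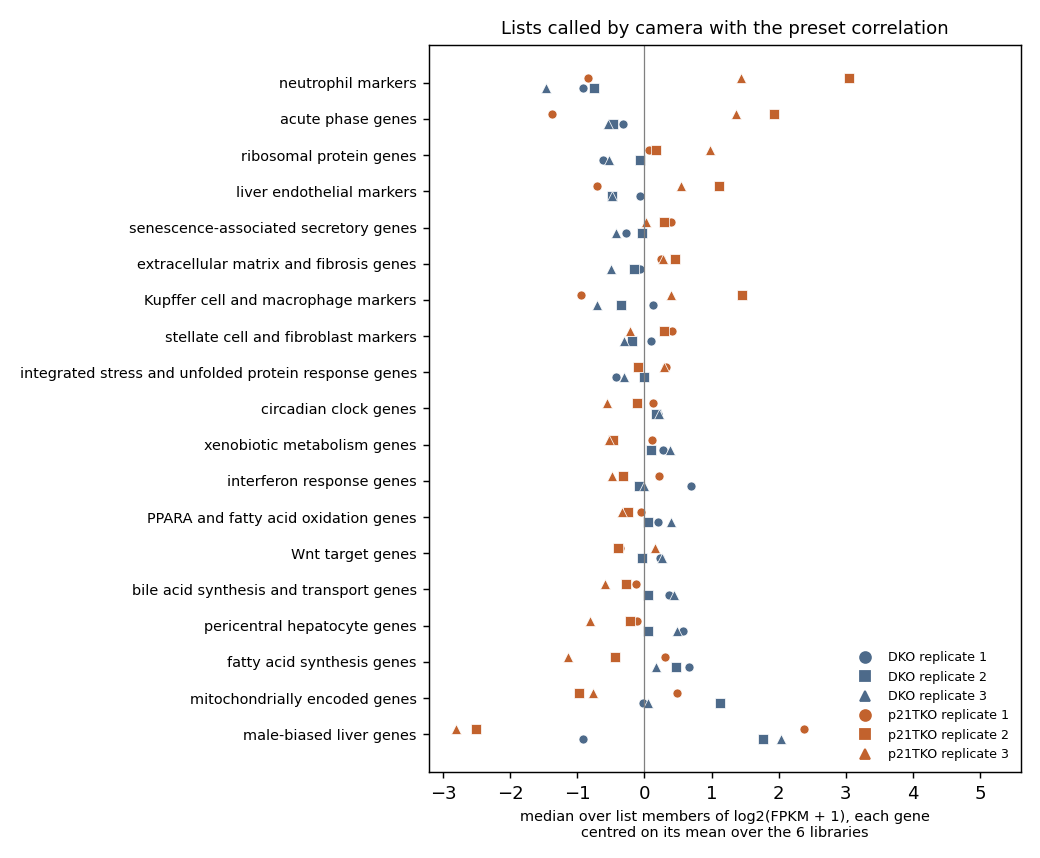
Median over list members of log2(FPKM + 1), each gene centred on its mean over the 6 libraries, for the 19 lists called by camera with the preset correlation, with a point for each library. For neutrophil markers p21TKO replicates 2 and 3 stood at 3.04 and 1.44 and p21TKO replicate 1 at -0.84, among the DKO libraries (-1.47 to -0.75).

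The cell cycle lists closest to p21 did not pass the test. Of the E2F G1/S genes, which act in DNA replication, 7 of 33 were expressed enough to test, 3 with higher and 4 with lower values (camera adjusted p = 0.8128). Pcna stood at 9.04 ± 0.892 FPKM in DKO and 12.5 ± 3.51 FPKM in p21TKO. The subunits of the DREAM, MMB and RB complexes (camera adjusted p = 0.8732), with Lin37 at 2.95 ± 0.582 and 4.69 ± 0.9 FPKM, did not pass. The cyclin D, CDK and CDK inhibitor genes (camera adjusted p = 0.4674) and the p53 target genes (camera adjusted p = 0.7659) did not pass either. Cdk6 stood at 1.77 ± 0.09 and 1.02 ± 0.303 FPKM. These p-values do not show that the groups were alike.

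Wnt target genes were lower as a list in the libraries labelled p21TKO, and Notch pathway genes were not. Of 10 tested Wnt targets, 8 had lower values, with a median log2 difference of -0.46 (camera adjusted p = 0.0115, and adjusted p = 0.594 with an estimated correlation). Only p21TKO replicates 1 and 2 lay below the DKO libraries (centred median -0.37 and -0.39), and p21TKO replicate 3 (0.16) lay among them (-0.03 to 0.26). Tnfrsf19 stood at 1.75 ± 0.614 FPKM in DKO and 0.759 ± 0.266 FPKM in p21TKO, and Rnf43 and Znrf3, which encode ubiquitin ligases that remove Wnt receptors, at 2.75 ± 0.883 against 1.70 ± 0.716 and 1.73 ± 0.139 against 1.15 ± 0.518 FPKM. The call was lost without p21TKO replicate 1 (adjusted p = 0.1426) or replicate 2 (adjusted p = 0.0831), and with no filter on low values the median was -0.03 (adjusted p = 0.5319). The Wnt ligands, receptors and transducers did not pass (camera adjusted p = 0.3062), although the Frizzled receptor genes Fzd8 (2.82 ± 0.497 and 1.10 ± 0.408 FPKM), Fzd4 (4.64 ± 0.394 and 2.73 ± 0.671 FPKM) and Fzd7 (3.08 ± 0.923 and 1.48 ± 0.287 FPKM) were among their lower values. The Notch ligands, receptors and transducers, 6 with higher and 7 with lower values, did not pass (camera adjusted p = 0.888).

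Pericentral, bile acid, fatty acid synthesis and fatty acid oxidation genes were lower as lists, while periportal, cholesterol synthesis and gluconeogenesis and glycolysis genes did not pass. Of 19 tested pericentral genes, which hepatocytes next to the central vein express, 17 had lower values (median log2 difference -0.72, camera adjusted p = 1e-05, and adjusted p = 0.594 with an estimated correlation). Rhbg, an ammonium transporter gene, fell from 2.53 ± 0.23 to 1.04 ± 0.283 FPKM when adjusted over the list alone (limma adjusted p = 0.0352), and Cyp2a5 stood at 1140.5 ± 60.98 and 482 ± 233 FPKM. Bile acid synthesis and transport genes were lower too (18 of 21, median -0.61, camera adjusted p = 1.77e-04, and adjusted p = 0.594 with an estimated correlation), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 53.2 ± 35.9 and 9.96 ± 11.3 FPKM. Fatty acid synthesis genes had 16 of 17 lower values (median -0.78, camera adjusted p = 1.54e-04, and adjusted p = 0.594 with an estimated correlation), with the regulator Mlxipl at 18.9 ± 1.90 and 7.22 ± 5.21 FPKM and Scd1 at 846 ± 243 and 314 ± 434 FPKM. PPARA and fatty acid oxidation genes had 24 of 29 (median -0.45, camera adjusted p = 3.71e-04, and adjusted p = 0.594 with an estimated correlation), with Cpt1a, which admits fatty acids to mitochondria, at 56.8 ± 10.3 and 30.9 ± 4.91 FPKM. These 4 lists passed whichever library was left out, and without p21TKO replicate 3 the medians of the last 2 were -0.42 and -0.27. For fatty acid synthesis p21TKO replicate 1 lay among the DKO libraries (centred median 0.31 against 0.17 to 0.66) and p21TKO replicates 2 and 3, which had the highest acute phase and neutrophil medians, lay below them (-0.43 and -1.14). Its median difference was -1.42 within libraries without Y-linked transcripts and -0.06 within those with them. In the same order the medians were -1.03 and -0.415 for pericentral genes and -0.72 and -0.34 for bile acid genes. For fatty acid oxidation genes they were -0.44 and -0.155. The pericentral and bile acid lists share Cyp7a1 and Cyp27a1, so they are not separate evidence. The xenobiotic metabolism genes (22 of 32, median -0.37, camera adjusted p = 0.031, and adjusted p = 0.594 with an estimated correlation) did not pass without DKO replicate 1 (adjusted p = 0.2186) or p21TKO replicate 2 (adjusted p = 0.0855), nor with mitochondrial genes left out of the total (adjusted p = 0.0737). Their median ranged from -0.65 to -0.28 when a library was left out. For them p21TKO replicate 1 (centred median 0.11) lay among the DKO libraries (0.1 to 0.38), and p21TKO replicates 2 and 3 lay below (-0.47 and -0.52). Their median difference was -0.67 within libraries without Y-linked transcripts and -0.09 within those with them. Periportal genes (camera adjusted p = 0.8549, camera direction up, median -0.10) and the hepatocyte markers (camera adjusted p = 0.4674) did not pass.

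Acute phase genes and neutrophil markers were higher as lists, and the higher list medians came from p21TKO replicates 2 and 3. Of 25 tested acute phase genes, 23 had higher values (median log2 difference 1.03, camera adjusted p = 0.0016, and adjusted p = 0.765 with an estimated correlation), yet p21TKO replicate 1 lay below all DKO libraries (centred median -1.38 against -0.54 to -0.32). Orm1, an acute phase glycoprotein gene, stood at 1368 ± 224 FPKM in DKO and 5789 ± 4350 FPKM in p21TKO, and Socs3, a cytokine signalling inhibitor gene, at 4.39 ± 1.495 and 16.3 ± 12.0 FPKM. The median of the acute phase genes was 1.94 without p21TKO replicate 1, and the list did not pass without p21TKO replicate 2 (0.35, adjusted p = 0.4285) or with a sex term (median 0.47, adjusted p = 0.0836). Neutrophil markers were higher in 9 of 9 tested genes (median 2.35, camera adjusted p = 3.85e-05, and adjusted p = 0.594 with an estimated correlation), with S100a8 at 4.54 ± 3.31 and 89.1 ± 87.5 FPKM and Retnlg at 0.917 ± 0.705 and 27.2 ± 25.1 FPKM. That list passed whichever library was left out, with medians from 1.27 without p21TKO replicate 2 to 3.45.

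**Figure D5:**
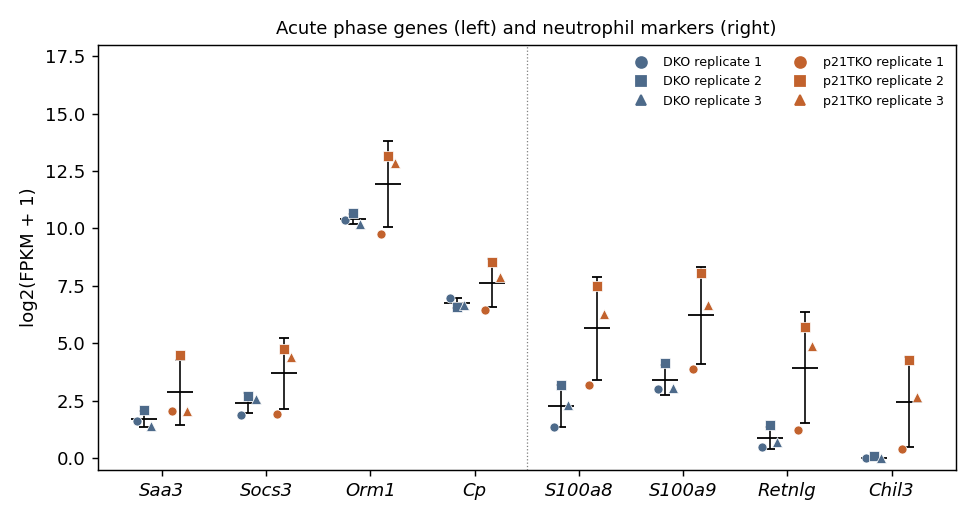
Expression of 4 acute phase genes and 4 neutrophil markers in each library as log2(FPKM + 1), with bars for the mean and SD of 3 libraries per group. For S100a8 p21TKO replicates 2 and 3 stood at 181.79 and 77.47 FPKM and the other 4 libraries at 8.1 FPKM or below.

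Markers of other nonparenchymal cells were higher as lists in part. Liver endothelial markers had 16 of 16 higher values (median 0.69, camera adjusted p = 2.56e-04, and adjusted p = 0.748 with an estimated correlation), with Pecam1 at 1.32 ± 0.207 and 4.04 ± 2.81 FPKM, and did not pass without p21TKO replicate 2 (0.27, adjusted p = 0.1288). Leaving out each library in turn gave medians from 0.27 to 1.17. As with the acute phase genes, p21TKO replicate 1 lay below the DKO libraries (centred median -0.70 against -0.48 to -0.07), and its centred median for Kupffer cell markers was -0.94 against -0.71 to 0.13. Kupffer cell and macrophage markers had 14 of 14 (median 0.48, camera adjusted p = 0.026, and adjusted p = 0.838 with an estimated correlation), with the scavenger receptor gene Marco at 2.18 ± 1.26 and 23.9 ± 22.6 FPKM. The median of the Kupffer cell and macrophage markers was 1.13 without p21TKO replicate 1 and 0.021 without p21TKO replicate 2 (adjusted p = 0.7757, camera direction down). The list did not pass without DKO replicate 2, DKO replicate 3 or p21TKO replicate 3 (adjusted p = 0.0815, 0.1926 and 0.0547), with a sex term (adjusted p = 0.5244) or with voom (adjusted p = 0.0513). The stellate cell and fibroblast markers (8 of 11, median 0.23, camera adjusted p = 0.0243, and adjusted p = 0.736 with an estimated correlation), with Dcn at 11.6 ± 5.11 and 24.9 ± 9.795 FPKM, did not pass without DKO replicate 2, DKO replicate 3, p21TKO replicate 1 or p21TKO replicate 2 (adjusted p = 0.0596, 0.1001, 0.5243 and 0.0762). Their median ranged from 0.145 to 0.352 when a library was left out. For these markers p21TKO replicate 3 (centred median -0.22) lay among the DKO libraries (-0.3 to 0.1), and p21TKO replicates 1 and 2 lay above (0.41 and 0.29). The extracellular matrix and fibrosis genes (7 of 9, median 0.51, camera adjusted p = 0.0197, and adjusted p = 0.594 with an estimated correlation), with the basement membrane gene Col4a2 at 0.824 ± 0.21 and 2.78 ± 1.47 FPKM, did not pass without DKO replicate 3, p21TKO replicate 1 or p21TKO replicate 2 (adjusted p = 0.0807, 0.0696 and 0.0762). The senescence-associated secretory genes (14 of 19, median 0.54, camera adjusted p = 0.0056, and adjusted p = 0.594 with an estimated correlation), with Igfbp6 at 0.802 ± 0.177 and 3.35 ± 1.95 FPKM and Timp2 at 2.04 ± 0.35 and 3.49 ± 0.37 FPKM, did not pass without DKO replicate 3 (0.32, adjusted p = 0.0807) or p21TKO replicate 1 (0.35, adjusted p = 0.0659), nor at a mean FPKM of at least 5 (adjusted p = 0.1768). Erythroid markers did not pass (camera adjusted p = 0.8214).

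Ribosomal protein genes were higher and mitochondrially encoded genes lower, both whichever library was left out. All 44 ribosomal protein genes had higher values (median 0.78, camera adjusted p = 9.53e-16, and adjusted p = 0.594 with an estimated correlation), and for 25 of them the groups did not overlap, against 15.4% of all tested genes and 10% by chance, although these genes vary together (estimated inter-gene correlation 0.799). Without p21TKO replicate 3 the median of the ribosomal protein genes was 0.50. Rps29 stood at 160.0 ± 49.2 and 460 ± 196 FPKM and Rps3 at 57.5 ± 4.28 and 110 ± 39.7 FPKM. Of 13 mitochondrially encoded genes, 12 had lower values (median -0.80, camera adjusted p = 7.47e-04, and adjusted p = 0.748 with an estimated correlation). Without DKO replicate 2 the median of the mitochondrially encoded genes was -0.41 (adjusted p = 0.0411) and without p21TKO replicate 1 it was -1.25, as p21TKO replicate 1 lay among the DKO libraries (centred median 0.49 against -0.02 to 1.12). mt-Nd4l fell from 206 ± 25.5 to 36.3 ± 22.5 FPKM when adjusted over the list alone (limma adjusted p = 0.0068). Mitochondrially encoded genes took 7.2%, 13.0% and 7.3% of recovered reads in DKO and 8.5%, 3.7% and 5.2% in p21TKO. The nuclear respiratory chain genes did not pass (median 0.10, camera adjusted p = 0.3043). They were higher with a sex term (0.24, adjusted p = 6.25e-04, and adjusted p = 0.621 with an estimated correlation), without DKO replicate 2 (adjusted p = 0.0411) and without p21TKO replicate 3 (adjusted p = 0.0327). The integrated stress and unfolded protein response genes were higher in 20 of 24 (median 0.21, camera adjusted p = 0.0058, and adjusted p = 0.594 with an estimated correlation), with the endoplasmic reticulum genes Sdf2l1 at 17.1 ± 2.66 and 57.1 ± 24.0 FPKM and Pdia4 at 48.7 ± 3.94 and 87.2 ± 5.08 FPKM. That call was lost without DKO replicate 1 (adjusted p = 0.0507) or p21TKO replicate 1 (adjusted p = 0.0866), and without DKO replicate 2 the median was 0.62.

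Interferon response, circadian clock and male-biased liver genes were lower as lists. The interferon response genes had 25 of 28 lower values (median -0.43, camera adjusted p = 0.0013, and adjusted p = 0.748 with an estimated correlation), with Iigp1 at 59.9 ± 18.8 and 31.3 ± 16.3 FPKM, and did not pass without DKO replicate 1 (-0.20, adjusted p = 0.4132). For them too p21TKO replicate 1 lay among the DKO libraries (centred median 0.22 against -0.08 to 0.70), and the median difference was -1.10 within libraries without Y-linked transcripts and 0.28 within those with them. The circadian clock genes had 13 of 17 (median -0.30, camera adjusted p = 0.0271, and adjusted p = 0.748 with an estimated correlation), with the clock output gene Dbp at 31.0 ± 2.17 and 11.1 ± 11.5 FPKM, and did not pass without DKO replicate 2 (adjusted p = 0.0815), without p21TKO replicate 3 (adjusted p = 0.1901) or with a sex term (adjusted p = 0.0622), nor at a mean FPKM of at least 5 (adjusted p = 0.0539). The median of the clock genes ranged from -0.52 to -0.15 when a library was left out. It was -0.60 within libraries without Y-linked transcripts and -0.02 within those with them. The male-biased liver genes had 22 of 23 (median -1.78, camera adjusted p = 0.0019, and adjusted p = 0.765 with an estimated correlation), and with a sex term the median was -0.58 (adjusted p = 0.3257). It was -1.08 within libraries without Y-linked transcripts and 0.41 within those with them, where p21TKO replicate 1 had the highest centred median of all libraries (2.37). Their median ranged from -3.65 without p21TKO replicate 1 to -0.99 without p21TKO replicate 3 (adjusted p = 0.0714), and they did not pass without DKO replicate 2 (adjusted p = 0.0505) or p21TKO replicate 2 (adjusted p = 0.0919). The female-biased liver genes did not pass (median -0.22, camera adjusted p = 0.7135) and did with a sex term (median -1.28, camera adjusted p = 1.68e-06, and adjusted p = 0.621 with an estimated correlation). Their median difference was -2.53 within libraries without Y-linked transcripts and -0.002 within those with them. DKO replicate 1, the only DKO library without Y-linked transcripts, had the highest centred median (3.15). Without it every DKO library had Y-linked transcripts, and the median was 1.004 in the other direction (camera adjusted p = 4.42e-07).

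The remaining lists did not pass by camera as fitted without a sex term over all 6 libraries. They were the genes of cholesterol synthesis (camera adjusted p = 0.7135, camera direction up, median -0.004), gluconeogenesis and glycolysis (0.5309), MHC and antigen presentation (0.4674), NRF2 targets (0.991, median -0.08 and mean 0.01), heat shock (0.2303), DNA damage response and repair (0.6497), telomeres and telomerase (0.4674), apoptosis regulation (0.4674) and the immediate early response (0.3062, camera direction up, median -0.12). With a sex term the heat shock genes (median 0.64, adjusted p = 0.0021, and adjusted p = 0.621 with an estimated correlation) and the immediate early genes (0.55, adjusted p = 0.015, and adjusted p = 0.725 with an estimated correlation) were higher. The heat shock genes also passed without DKO replicate 2 (adjusted p = 0.0489) or p21TKO replicate 3 (adjusted p = 0.0021). The immediate early genes passed without DKO replicate 2 (adjusted p = 0.0027). The cholesterol synthesis genes passed without DKO replicate 1 (adjusted p = 0.0073) or p21TKO replicate 1 (adjusted p = 0.0284). Their median ranged from -0.17 to 0.52 when a library was left out. These genes vary together (estimated inter-gene correlation 0.628), and with that correlation camera gave an adjusted p of 0.927 over all 6 libraries. Among the remaining lists, the heme oxygenase gene Hmox1 stood at 10.2 ± 3.11 and 38.4 ± 25.7 FPKM and Gadd45b at 1.05 ± 0.347 and 7.02 ± 4.95 FPKM in DKO and p21TKO.

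The ssGSEA scores, the analysis named for this series, gave non-overlapping groups for 7 of 39 lists, where chance gives 10%. The difference in score had the sign of the camera call in 19 of 19 called lists. The scores rank the same values of the same genes that camera used, so a shared sign is not independent support. With a sex term, taken from the Y-linked transcripts after they were seen, 15 of the 19 lists were called in the same direction. The female-biased, heat shock, immediate early and nuclear respiratory chain genes were called in addition (0 lists with an estimated correlation). Of the 19 lists the median difference had the same sign within both sexes for 14. It turned for the acute phase, Kupffer cell, endothelial, interferon response and male-biased genes.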

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

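The alternatives with a sex term, without pseudogenes, without mitochondrial genes in the total and for the ssGSEA scores were chosen after the values were seen. The count of genes higher in p21TKO (3) was 5 with a pseudocount of 0.1, 0 with no filter on low values, 0 with limma voom on recovered reads, 1 with voom and a sex term and 0 with pseudogenes left out. The count lower (4) was 1 with no filter, 2 at a mean FPKM of at least 5, 1 with voom and 1 with voom and a sex term. With the replicate number as a block both counts were 0. The labels state no pairing by number. Deviations of same-numbered libraries correlated at -0.44, -0.49 and -0.07, and 0 libraries correlated best with their own number. Same-numbered libraries always differed in Y-linked transcripts, so these correlations cannot exclude a pairing. The block called 19 lists. Leaving out 1 library in turn gave 0 to 225 genes higher and 1 to 270 lower, the highest without p21TKO replicate 1. The cause was not tested. All 7 calls were kept under both scalings, without trend, with robust eBayes, with a pseudocount of 0.1 and with a sex term, and the median difference of all genes was 0.002, and 0.011 and 0.027 after the scalings. The count of called lists (19) was 12 at a mean FPKM of at least 5, where fewer genes are tested. It was 0 with an estimated correlation (0 also with a sex term), 0 with fry and 0 with limma on ssGSEA scores. When a library was left out the count was 11 to 19, newly called lists included. Of the original 19 lists, 11 to 16 stayed called in the same direction each time, and 7 passed whichever library was left out. Scores called by ssGSEA (0) were 0 to 3 when a library was left out. The Cdkn1a difference (1.66) ranged from 1.16 without p21TKO replicate 2 to 2.32 without p21TKO replicate 1, was 2.36 with a pseudocount of 0.1 and 2.56 with voom, and Cdkn1a could not be tested at a mean FPKM of at least 5. When a library was left out, the median of female-biased genes ranged from -0.881 to 1.004, the latter called without DKO replicate 1 (-1.28 with a sex term and -2.34 with voom and a sex term), and that of Kupffer cell markers from 0.021, where the direction by camera turned to lower, to 1.13. Of the other values, 3005 for single genes kept their side of the threshold, 41 gained and 48 lost it, and for lists 732 kept, 17 gained and 98 lost it. Of those that kept it, 20 for genes and 56 for lists had the other sign and passed in neither. Each read in 1 kb of exon gave 0.037 to 0.0516 FPKM, so short genes near 1 FPKM rest on few reads. Depth was not tested as a limit.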

Other observations

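The tests of explanations and of other splits and the estimated correlations given here were chosen after the results were seen. 6 fixed lists had fewer than 5 tested members and were compared only with no filter on low values. T, B and NK cell markers were lower (22 genes, median log2 difference -0.18, camera adjusted p = 4.42e-09, and adjusted p = 0.621 with an estimated correlation), and cholangiocyte markers were higher (15 genes, median 0.16, camera adjusted p = 0.0013, and adjusted p = 0.621 with an estimated correlation). Their medians lay at 0.308 to 0.339 FPKM in DKO and 0.052 to 0.164 FPKM in p21TKO for the lymphocyte markers, and at 0.069 to 0.114 and 0.152 to 0.352 FPKM for the cholangiocyte markers. The 4 lymphocyte markers with a mean FPKM of at least 1 were divided and did not pass. Igkc (0.16) and Jchain (0.08) had higher values, and Ighm (-0.39) and Ccl5 (-0.50) lower ones. MMB-FOXM1 G2/M genes, expressed in dividing cells, did not pass (34 genes, median -0.01, camera adjusted p = 0.3715), nor did Notch target genes (11 genes, median 0.06, camera adjusted p = 0.0887), exocrine pancreas markers (camera adjusted p = 0.9943) or adipocyte markers (camera adjusted p = 0.9943). The medians of all 6 lists lie near the floor of the data. Some members do not, such as Car3 of the adipocyte markers (315 to 881 FPKM in DKO and 0.439 to 1341 FPKM in p21TKO).

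For Cdkn1a transcripts in the libraries labelled p21TKO, nothing in the tables decides between a transcript of the disrupted allele and wrong labels. The lowest read number was 97 in p21TKO and 32 in DKO, so no library stood near 0, and gene-level values over all exons cannot show whether the deleted part is covered. If 1 library of each group had been exchanged, another split could separate more genes. Over all autosomal genes the labelled split separated 31 by a log2 gap of at least 1 and the split by Y-linked transcripts 72. That split is also the one that exchanging replicate 1 of each group would give. The count therefore cannot tell sex from such an exchange and leaves the exchange open. A count restricted to genes near Cdkn1a and pseudogenes with a parent there, tried after that one had decided nothing, gave 6 against at most 1 in another split, but without the pseudogenes 2 against 1, so it leaves the exchange open too.

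For the genes near Cdkn1a that separate the groups, a candidate explanation is that DNA around the knockout allele came from another mouse strain. Such DNA could change both expression and how reads map. A segment around Cdkn1a does not bear on Ctse, Ren1 or A2ml1, which lie on chromosomes 1 and 6. The odds ratio of 3.14 near Cdkn1a held above 1 in all 25 combinations of window (5 to 30 Mb) and p limit tried (1.46 to 5.86, Fisher's exact test p under 0.05 in 24), which is consistent with such a segment, although the genes behind it include small differences such as that of Tmem8 (-0.88). The parents of separating processed pseudogenes lay there more often as well (4 of 14 against 23 of 507, odds ratio 8.42, Fisher's exact test, two-sided p = 0.00403, and p = 0.0755 with a wider p limit, under 0.05 in 21 of 25 combinations). Of the 4 parents Atp6v0c (-1.03, SE 0.189) and Rnps1 (-1.33, SE 0.221) had lower values where the pseudogenes were higher. Neither passed on its own (limma adjusted p = 0.2522 and 0.1894). Rps2 (-0.11, SE 0.288) and Glo1 (0.65, SE 0.463) showed no such fall, but they cannot tell, as they held far more reads than their pseudogenes. In p21TKO these were 8128 to 15986 against 197 to 334 reads for Rps2 and 4826 to 13195 against 511 to 1208 reads for Glo1. Reads moving between copies therefore stay open. Strain segments elsewhere were tested too, and pairs within 5 Mb (76, mean 75.7 in 10000 draws, one-sided permutation p = 0.48) decided nothing. The densest 5 Mb stretch, tried after the pairs, lay on chromosome 1 from 128.4 Mb, with 6 of 29 genes separated, Ctse and Ren1 among them. It had a one-sided permutation p of 0.001, the smallest 1000 draws can give. A second strain segment would give such a stretch, so a strain origin stays open for Ctse and Ren1. For the called genes the mix of sexes is argued against, since 7 of 7 calls stayed with a sex term, and strains could not be compared because the labels give none.

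For the neutrophil markers, blood left in the tissue stays open. The ratio of S100a8 to the red cell gene Hba-a1 was 0.0172 to 0.0322 in the DKO libraries and p21TKO replicate 1. It was 0.498 and 6.4 in p21TKO replicates 2 and 3, so 2 p21TKO libraries lay over 5 times above the highest DKO ratio. Hba-a1 in p21TKO replicate 2 (364.9 FPKM) lay within the DKO range (72.2 to 403.6 FPKM). In p21TKO replicate 3 Hba-a1 lay below that range (12.1 FPKM), so S100a8 did not rise together with red cell RNA there. The makeup of the blood was not measured, so a higher ratio alone cannot decide. With a sex term the neutrophil median was 1.70 (camera adjusted p = 1.46e-04, and adjusted p = 0.621 with an estimated correlation), with 3.26 within libraries without Y-linked transcripts and 0.14 within those with them. For the acute phase genes the median with a sex term was 0.47 and the list was no longer called. For both lists the mix of sexes may contribute. The sex term parts sex from group only weakly, as there was 1 DKO library without Y-linked transcripts and 1 p21TKO library with them. Loss of p21 stays open, as for the acute phase genes 2 of 3 p21TKO libraries lay above every DKO library and p21TKO replicate 1 below them. Infection or illness of single animals was not tested.

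Other splits of the 6 libraries are too few (10) for a share under 0.05. The labelled split called 3 genes higher and 4 lower, and the highest other split called 30 in a direction, so 2 of 10 splits gave as many in each case. That other split is by Y-linked transcripts and is also the one that exchanging replicate 1 of each group would give. It points to a structure of the samples, but cannot tell these sources apart. The 19 lists called were matched by 1 of 10 splits, the labelled one itself. The other splits called 7 to 17 lists each, so camera with the preset correlation called many lists however the libraries were grouped. For ssGSEA scores all 10 splits gave at least 0, with 3 the highest of the others.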
